A study of Bos taurus with 56 samples.

How the data were processed

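Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into DNA that is not packed in closed chromatin, so that sequenced fragments pile up over accessible regions as peaks. The labels put 56 libraries from cattle (Bos taurus) into 11 groups, namely GV oocytes (6 libraries), MII oocytes (5), 2-cell embryos (6), 4-cell embryos (6), 8-cell embryos (5), 16-cell embryos (5), morulae (6), morulae labelled in vivo (4), blastocysts (3), blastocysts labelled in vivo (4) and day 14 elongating embryos (6). Per the series description, oocytes and embryos were pooled for sequencing, so that each library came from a pool. The groups without an in vivo label carry no statement of how their oocytes or embryos were produced.

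Per the series description, the authors merged the peaks of the individual libraries of a stage, and 1 merged list per group was deposited. Each list held 3 columns, the chromosome, start and end of each peak, and no score, height, fold enrichment, p-value or read count. Sequencing depth per library was therefore unknown. Per the submitters' processing notes, Bowtie2 2.3, MACS2, bedtools and HOMER were used with the cattle genome build UMD3.1. The order of the steps, the peak-calling threshold, any shift of reads for the transposase cut and the rule for merging are not given in the sources used here. Depth, the calling threshold and the merging rule each affect how many peaks a list holds, and a merged list keeps no record of how many of its libraries showed a peak.

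In all 11 lists the peaks lay on 29 autosomes and the X chromosome, and no peaks within a list overlapped. Positions on X ran to 148822422, with 1187 X peaks beyond the last gene on X in the gene table at hand, which is of another assembly, so that no coordinates of that table were used and no gene was assigned to any peak. Gene context, promoter peaks of fixed gene lists and sequence motifs had been planned and were not analysed here for that reason. The lists were read as BED files, counting the start from 0, and positions are printed counting from 1; the lists do not state this convention, and a start could be off by 1 base.

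Peak numbers, widths and covered bases were computed for each list, with chromosome lengths taken as the last position in any of the 11 lists, 2661 Mb in total. A peak was counted as shared when it overlapped a peak of the other list by at least 1 bp. For each comparison the text leads with the share of the shorter list found in the longer one, since this share is less limited by list length than its reverse. Each share has a 95% exact Clopper-Pearson interval, which covers counting error only and treats neighbouring peaks as independent. As a background, the peaks were placed at random on their own chromosome 100 times, keeping their widths, and the observed number was divided by the mean of these placements. The placements ignore gaps in the assembly. Peak density per chromosome was divided by the density of the whole list. A region of the union was made by joining overlapping peaks of all lists, and was assigned to each list with a peak in it.

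With 1 merged list per group the spread between replicate libraries could not be computed, so no p-value is given and differences between lists are described as values. Consecutive stages were compared in developmental order, and the lists labelled in vivo were compared with the lists of the same stage without that label. The regions named in the text followed a rule set before the data were examined, namely the widest peak of each list and, for each comparison, the 3 widest peaks not shared with the other list. Other regions named were chosen after their values were seen, and this is stated beside them.

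Alternatives set before the data were examined were joining peaks closer than 500 bp, keeping peaks of at least the median width of all peaks (329 bp), requiring 50% of both peaks to be shared, widening peaks by 250 bp on each side, drawing the longer list down to the length of the shorter one 100 times, and drawing random positions from the peaks of the other lists. Alternatives added after seeing the data weighted unshared peaks to the widths of shared peaks, by deciles of width within the list, and left out recurring regions, defined as regions found in 2 or more of the other short lists. The 6 short lists were those of both oocyte stages, the 2-cell and 4-cell embryos and both blastocyst groups. Overlap counts were tested on simulated lists with planted overlaps for the 10 comparisons, and all 10 planted counts were recovered. On the real lists, the counts for all 10 comparisons were equal to those of bedtools 2.31.1. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.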

Results

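Accessible chromatin was mapped in cattle oocytes at the germinal vesicle (GV) stage, when the immature oocyte is arrested in meiotic prophase, and at metaphase II (MII), when it is mature, and in embryos from the 2-cell stage to day 14. The embryonic stages span the activation of the bovine embryonic genome around the 8-cell to 16-cell stage, the formation of the blastocyst, and the elongating embryo at day 14. Peak numbers differed between stages by more than 2 orders of magnitude. The MII oocyte list was the shortest, with 730 peaks, and the day 14 list the longest, with 372509. The 8-cell, 16-cell and morula lists held 59186, 75925 and 88858 peaks, whereas the GV oocyte, 2-cell, 4-cell and blastocyst lists held 4382, 2636, 5810 and 3397. Among the lists labelled in vivo, the morula list held 57039 peaks and the blastocyst list 2587. Covered length ran from 0.276 Mb in MII oocytes, 0.0104% of the 2661 Mb spanned by the lists, to 124 Mb or 4.66% in day 14 embryos. Median peak width lay between 216 bp in the day 14 list and 551 bp in the in vivo morula list. The narrowest peak ranged from 125 bp in the day 14 list to 268 bp in the in vivo morula list, so the lists had different lower bounds of width. Each list was merged by the authors from 3 to 6 replicate libraries, so the spread between replicates could not be computed, and all differences are between single lists of unknown sequencing depth. When only peaks of at least 329 bp were counted, the MII, 2-cell, 16-cell, blastocyst and day 14 lists held 324, 1336, 50423, 1044 and 108850 peaks, and the other lists stayed within 1.5 times their full number.

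**Figure D1:**
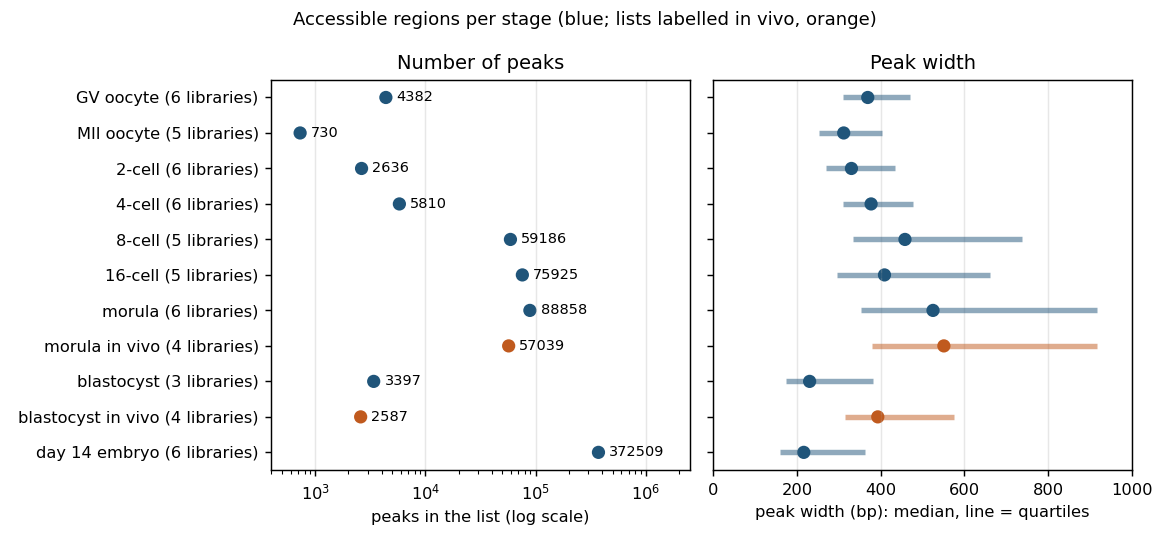
Number of peaks in each list (left, log scale) and peak width in bp (right, median as a point and quartiles as a line), with the lists labelled in vivo in orange. The 8-cell, 16-cell and both morula lists lie between 57039 and 88858 peaks, and the blastocyst lists hold 3397 and 2587.

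The GV oocyte list held 6.0 times as many peaks as the MII oocyte list and covered 1.89 Mb against 0.276 Mb. Peaks in GV oocytes were densest on chromosomes 18 (2.38 times the list mean), 13 (2.11 times) and 23 (1.92 times), and sparsest on chromosomes 22 (0.326 times) and 1 (0.395 times). On the gene-dense chromosomes 18, 19 and 25 together, peak density was 2.04 times that of the other chromosomes in GV oocytes and 1.20 times in MII oocytes. Of the MII peaks, 140 (19.2%, 95% interval 16.4% to 22.2%) overlapped a GV peak, against a mean of 1.07 peaks and a highest value of 4 in random placements. The widest GV peak, on chromosome X from 89972338 to 89976342 (UMD3.1, 4005 bp), and the widest MII peak, on chromosome 7 from 89222521 to 89224651 (2131 bp), each overlapped a peak in all 11 lists and thus belong to the regions that recur in the short lists. The 3 widest GV peaks without an MII peak lay on chromosome 18 from 57604364 to 57607874, on chromosome 9 from 39085 to 41598 and on chromosome 3 from 8109518 to 8111892. The region on chromosome 18 had peaks in the 2-cell, 4-cell, 8-cell and day 14 lists too, and in no morula or blastocyst list. The MII share was 11% when 50% of both peaks had to be shared, 3.12% with the GV list drawn down to the MII length, and 1.31% without recurring regions, and among peaks of at least 329 bp the GV list was 9.03 times as long as the MII list. Against positions drawn from peaks of the other lists, the observed number was 12.5 times the random one, and not 131 times as for whole chromosomes.

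After MII, the 2-cell list held 3.61 times as many peaks as the MII oocyte list, and the 4-cell list 2.20 times as many as the 2-cell list. Of the MII peaks, 170 (23.3%, interval 20.3% to 26.5%) overlapped a 2-cell peak, 246 times the random mean of 0.690. Of the 2-cell peaks, 693 (26.3%, interval 24.6% to 28%) overlapped a 4-cell peak, 125 times the random mean of 5.53. The widest 2-cell peak, on chromosome X from 89972470 to 89976216, lay in the same region as the widest GV peak. The widest 4-cell peak, on chromosome 3 from 8102265 to 8109236, spanned 6972 bp and likewise overlapped a peak in all 11 lists. Among 2-cell peaks absent from MII oocytes, the widest lay on chromosome 17 from 35644840 to 35648370, with peaks in all 9 embryo lists and in neither oocyte list. Behind it came the peaks on chromosome 15 from 3825 to 6992 and on chromosome 8 from 76341480 to 76344543, both of which were also found in GV oocytes. Among 4-cell peaks absent from 2-cell embryos, the widest lay on chromosome 29 from 5512512 to 5515272, on chromosome X from 58027786 to 58029995 and on chromosome 20 from 31672234 to 31673997. The region on chromosome 20 had peaks in the 8-cell, 16-cell, both morula and day 14 lists, and in no oocyte or blastocyst list. Most of this sharing lay in the recurring regions, and without them 0.374% of MII peaks were in the 2-cell list and 7.42% of 2-cell peaks in the 4-cell list. Those regions were selected for presence in several short lists, so leaving them out favours lower shares whatever their nature. The shares were 12.9% and 17.9% with 50% of both peaks shared and 6.42% and 12% with the longer list drawn down, and positions from other lists gave ratios of 16.8 and 12.1.

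Between the 4-cell and 8-cell stages the number of peaks differed by 10.2 times and the covered length by 13.8 times, from 2.66 Mb to 36.8 Mb. Of the 8-cell peaks, 56193 (94.9%) were in none of the GV, MII, 2-cell and 4-cell lists, a share that the shortness of those lists makes high whatever the positions. In the other direction, 1920 of the 4-cell peaks (33.0%, interval 31.8% to 34.3%) overlapped an 8-cell peak, 14.0 times the random mean. Those shared peaks recurred one division later, 76.0% of them overlapping a 16-cell peak, against 8.97% of the 4-cell peaks absent from the 8-cell list, or 11.8% when these were weighted to the widths of the shared ones. The widest 8-cell peak, on chromosome 8 from 80832687 to 80843559 (10873 bp), had peaks in the 4-cell, 16-cell, both morula and day 14 lists. The 3 widest 8-cell peaks without a 4-cell peak lay on chromosome X from 82265202 to 82274072, on chromosome 6 from 49138428 to 49147248 and on chromosome 7 from 17181990 to 17190337, with widths of 8348 to 8871 bp. The regions on chromosomes X and 6 had peaks in the 8-cell, 16-cell and both morula lists and in no other list. Peak density on chromosomes 18, 19 and 25 was 1.39 times that of the other chromosomes in 8-cell embryos and 1.01 times in 4-cell embryos. The share of 4-cell peaks was 14.9% with 50% of both peaks shared and 3.31% with the 8-cell list drawn down to the 4-cell length. Against positions drawn from other lists the ratio was 2.12.

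From the 8-cell stage to the morula, peak numbers were 1.28 times higher at the 16-cell stage than at the 8-cell stage and 1.17 times higher in the morula than at the 16-cell stage. Of the 8-cell peaks, 45% (interval 44.6% to 45.4%) overlapped a 16-cell peak, 13.6 times the random mean, and of the 16-cell peaks 47.2% (interval 46.8% to 47.5%) overlapped a morula peak, 11.1 times the random mean. A common set ran through these stages, with 18638 of the 8-cell peaks (31.5%) present in both the 16-cell and morula lists. Of that set 68.4% had a day 14 peak, against 17.5% of the 8-cell peaks in neither the 16-cell nor the morula list, or 19.6% at matched widths. Wide peaks were shared more often, with 82.8% of the widest quintile of 8-cell peaks in the 16-cell list and 21.7% of the narrowest quintile. The widest 16-cell peak, on chromosome 12 from 58059934 to 58067136 (7203 bp), was found in the 8-cell, 16-cell and both morula lists and in no other list. The widest morula peak, on chromosome 11 from 49963246 to 49974292 (11047 bp), had peaks in the 8-cell, 16-cell, in vivo morula and day 14 lists. Among 16-cell peaks absent from the 8-cell list, the widest lay on chromosome 2 from 120884006 to 120888442, on chromosome 7 from 79344588 to 79348705 and on chromosome 11 from 49421715 to 49425778. Among morula peaks absent from the 16-cell list, they lay on chromosome 12 from 70285512 to 70290313 and from 86100592 to 86105197 and on chromosome 13 from 22852544 to 22857139. All 3 of these morula regions were also found in the in vivo morula list. With 50% of both peaks shared, the shares were 26.1% for the 8-cell and 22.8% for the 16-cell peaks. Positions drawn from other lists gave ratios of 2.46 and 2.02.

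**Figure D2:**
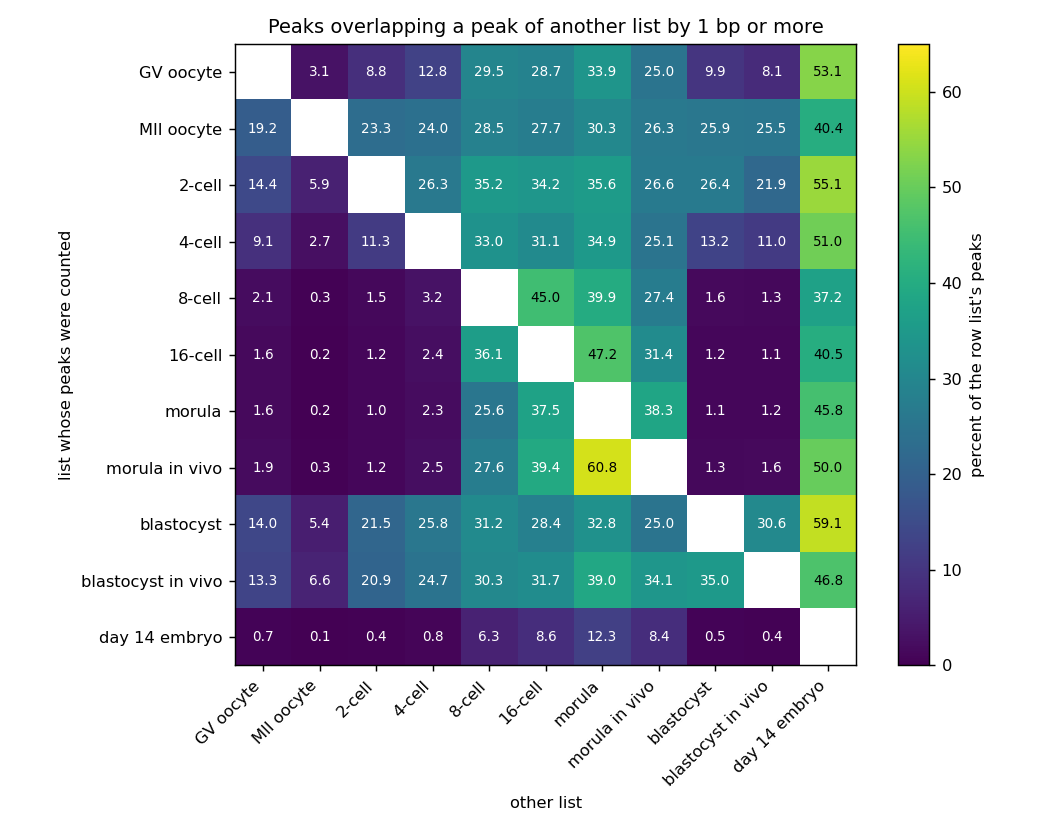
Percent of the peaks of each list (vertical axis) that overlap a peak of each other list (horizontal axis) by 1 bp or more. The highest value is 60.8%, for in vivo morula peaks found in the morula list, and shares within the short lists also depend on the length of the other list.

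The blastocyst list was far shorter than the morula list, which held 26.2 times as many peaks and covered 52.2 times as many bases. Among peaks of at least 329 bp the morula list held 71395 and the blastocyst list 1044, a ratio of 68.4. Of the blastocyst peaks, 1115 (32.8%, interval 31.2% to 34.4%) overlapped a morula peak, 9.18 times the random mean, and 1.13% of the morula peaks overlapped a blastocyst peak. Part of the blastocyst list lay in a few 1 Mb windows, the 10 fullest of which held 25.3% of its peaks. The windows named here were chosen after their values were seen, with 145 of the 197 peaks of chromosome 27 between 28 and 29 Mb, 116 of the 164 of chromosome 29 between 30 and 31 Mb and 129 of the 217 of chromosome 14 between 0 and 1 Mb. With these windows the density was 3.40, 2.49 and 2.01 times the list mean on chromosomes 27, 29 and 14, and without them 0.917, 0.744 and 0.824 times. In vivo, the windows held 21 of 72 peaks on chromosome 27, 63 of 93 on chromosome 29 and 60 of 139 on chromosome 14. In vivo densities on these chromosomes were 1.63, 1.86 and 1.69 times the list mean with the windows, and 1.18, 0.611 and 0.971 times without. Without their fullest window, chromosomes 17, 8 and X stayed above the mean, at 1.30 against 2.01 times, 1.23 against 1.98 times and 1.69 against 1.92 times, whereas chromosomes 18 (0.273 times) and 22 (0.281 times) were sparse. For chromosome 17 this left out only the window between 51 and 52 Mb, with 70 of its 193 peaks. A further 43 lay between 50 and 51 Mb and 36 between 25 and 26 Mb. The density without these windows too was not computed, so chromosome 17 is not shown to be dense outside them. On X the window left out lay between 37 and 38 Mb, with 46 of 364 peaks, and on chromosome 8 between 74 and 75 Mb, with 110 of 287. The next X window, between 36 and 37 Mb, held 9 regions found in 4 or more short lists. No further window was left out on X or chromosome 8, so neither is shown to be dense outside its clusters. On chromosomes 18, 19 and 25 together the density was 0.365 times that of the other chromosomes, against 0.942 times in the morula. The X chromosome held 10.7% (interval 9.69% to 11.8%) of blastocyst peaks and 4.26% (interval 4.13% to 4.39%) of morula peaks. The 3 widest morula peaks without a blastocyst peak lay on chromosome 11 from 49963246 to 49974292, on chromosome 10 from 42662704 to 42672464 and on chromosome 12 from 58059871 to 58069049. The region on chromosome 10 was found in the in vivo blastocyst list, and the regions on chromosomes 11 and 12 in neither blastocyst list. The share of blastocyst peaks was 17.6% with 50% of both peaks shared, 1.27% with the morula list drawn down, and 14.4% without recurring regions. Against positions drawn from the other lists the ratio was 1.18, above all 100 draws, with recurring regions kept in.

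Day 14 embryos had 110 times as many peaks as blastocysts and covered 124 Mb against 1.26 Mb. Of the day 14 peaks, 303808 (81.6%) were in no other list, a high share being set in part by the length of this list. Of the blastocyst peaks, 2009 (59.1%, interval 57.5% to 60.8%) overlapped a day 14 peak, 7.35 times the random mean. Day 14 peaks were densest on the gene-dense chromosomes 19 (2.27 times the list mean), 25 (2.12 times) and 18 (1.78 times) and sparsest on X (0.183 times). The X chromosome held 1.02% (interval 0.992% to 1.06%) of day 14 peaks, the lowest share among the 11 lists. The widest blastocyst peak, on chromosome 17 from 25029576 to 25044531 (14956 bp), and the widest day 14 peak, from 25029759 to 25044564 (14806 bp), were in the same place. That region had peaks in all 9 embryo lists and in neither oocyte list. The 3 widest day 14 peaks without a blastocyst peak lay on chromosome 22 from 60020261 to 60028088, on chromosome 26 from 51474440 to 51481927 and on chromosome 7 from 2890649 to 2897841. The region on chromosome 26 was found in the day 14 list alone, and that on chromosome 22 also in both morula lists. With the day 14 list drawn down to the blastocyst length, 0.563% of blastocyst peaks were shared. Positions drawn from other lists gave a ratio of 1.56.

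**Figure D3:**
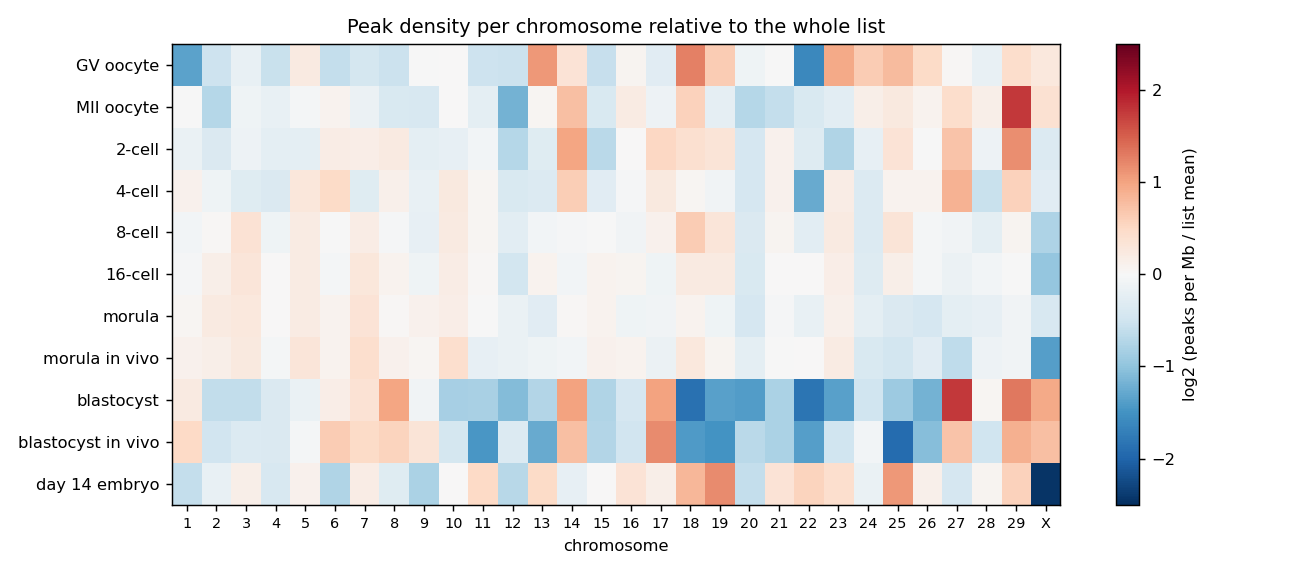
Peak density of each list (vertical axis) on each chromosome (horizontal axis), as log2 of peaks per Mb over the mean of that list. Both blastocyst lists are sparse on chromosomes 18, 19 and 25 and dense on X, and the day 14 list shows the opposite.

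Morulae labelled in vivo had a list 0.642 times as long as morulae without that label and shared most of it with them. Of the in vivo morula peaks, 34705 (60.8%, interval 60.4% to 61.2%) overlapped a peak of the other morula list, 12.6 times the random mean. That share was above the 39.4% found in the 16-cell list and the 27.6% found in the 8-cell list, both of which are shorter than the morula list. Peaks shared between the morula lists had a median width of 948 bp in the morula list without the label, against 409 bp for its unshared peaks. Of those shared peaks 59.8% were in the 16-cell list and 67.8% in the day 14 list, against 23.6% and 32.1% of the unshared ones, or 44.7% and 41.6% when the unshared peaks were weighted to the widths of the shared ones. Peaks found in vivo and absent from the other morula list overlapped a 16-cell peak in 8.55% of cases and a day 14 peak in 24.4%. The X chromosome held 2.17% (interval 2.05% to 2.29%) of in vivo morula peaks and 4.26% of the other morula peaks. The widest in vivo morula peak, on chromosome 17 from 25033165 to 25044772 (11608 bp), lay in the region of the widest blastocyst and day 14 peaks. The 3 widest unshared peaks belonged to the morula list without the label and lay on chromosome 2 from 80651803 to 80656383, on chromosome 7 from 112591230 to 112595807 and on chromosome X from 108858647 to 108863185. All 3 regions had peaks in the 8-cell and 16-cell lists. The in vivo share was 36.2% with 50% of both peaks shared and 39.8% with the longer list drawn down. Positions drawn from other lists gave a ratio of 2.56.

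In vivo blastocysts had 0.762 times as many peaks as blastocysts without that label and covered 1.17 times as many bases, with a median peak width of 393 bp against 230 bp. The narrowest peak was 241 bp wide in vivo and 137 bp without the label. Whether the peaks of both lists were called with the same settings is unknown, so the widths are not shown to differ between embryos. Among peaks of at least 329 bp the direction was reversed, with 1794 peaks in vivo against 1044, 1.72 times as many. Of the in vivo peaks, 905 (35%, interval 33.1% to 36.9%) overlapped a peak of the other blastocyst list, 241 times the random mean of 3.76. In the far longer morula lists, 39.0% overlapped a peak of the list without the label, 9.33 times the random mean, and 34.1% a peak of the in vivo list, 12.9 times. Both blastocyst lists were sparse on chromosomes 18, 19 and 25, at 0.365 times the density of the other chromosomes without the label and 0.324 times in vivo. Of the blastocyst peaks shared with the in vivo list 94.6% had a day 14 peak, against 43.5% of the unshared ones, but the shared peaks were wider (median 461 bp against 197 bp), and at matched widths the share of the unshared ones was 66.9%. Recurring regions were not left out of these shares and may account for the rest. Of the 511 regions found in 4 or more short lists, 98.2% had a day 14 peak. The widest in vivo blastocyst peak lay on chromosome 17 from 50865693 to 50875751 (10059 bp) and had peaks in all 9 embryo lists and in neither oocyte list. The 3 widest unshared peaks lay on chromosome X from 102771729 to 102777738 and on chromosome 21 from 59331998 to 59334233, both in vivo, and on chromosome 1 from 145440679 to 145442704, in the list without the label. The in vivo share was 22.3% with 50% of both peaks shared and 19% without recurring regions. Positions drawn from other lists gave a ratio of 16.7.

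The regions of chromosome 17 that held the widest peaks of 4 lists were followed through all stages, over spans chosen after the peaks were seen. From 25000001 to 25150000, no base was covered in either oocyte list, 4.12% in 2-cell, 3.96% in 4-cell, 6.59% in 8-cell and 6.83% in 16-cell embryos. Coverage there was 10.8% in morulae, 24.5% in in vivo morulae, 17.3% in blastocysts, 16.0% in in vivo blastocysts and 48.8% at day 14. The order differed when coverage was divided by the mean coverage of each list. It was then 366 times in blastocysts, 290 times in in vivo blastocysts, 95.6 times in 2-cell and 39.6 times in 4-cell embryos. The in vivo morula list had 15.3 times, day 14 10.5 times, and the 8-cell, 16-cell and morula lists 4.35 to 4.76 times. From 50850001 to 50950000, again no base was covered in oocytes, and coverage was 18% in 2-cell, 18.3% in 4-cell, 19.4% in 8-cell and 23.8% in 16-cell embryos. It was 28.2% in morulae, 36.2% in in vivo morulae, 27.4% in blastocysts, 36.6% in in vivo blastocysts and 31.2% at day 14. Over the mean of each list it was 663 times in in vivo blastocysts, 580 times in blastocysts, 418 times in 2-cell and 183 times in 4-cell embryos. The 8-cell, 16-cell and both morula lists had 11.4 to 22.7 times, and day 14, the lowest of the embryo lists, 6.69 times. The GV list, with 4382 peaks, was longer than the 2-cell list with 2636, so coverage in these spans did not follow list length. But the spans were picked for wide embryo peaks, and the GV list held only 1.36 peaks per Mb on chromosome 17. At that average density, spans of 150 and 100 kb without a GV peak are likely, and the absence is not shown to exceed this. Regions found in the 2-cell, 4-cell and both blastocyst lists give another yardstick. Of these 421 regions 58.0% were also in the GV list, but none of the 16 between 50 and 52 Mb, where the second span lies. Those 16 are neighbours in windows chosen after their values were seen, so they do not settle the question. Sequencing depth of the oocyte libraries is unknown, and whether the oocyte lists would hold peaks there at another depth was not tested.

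**Figure D4:**
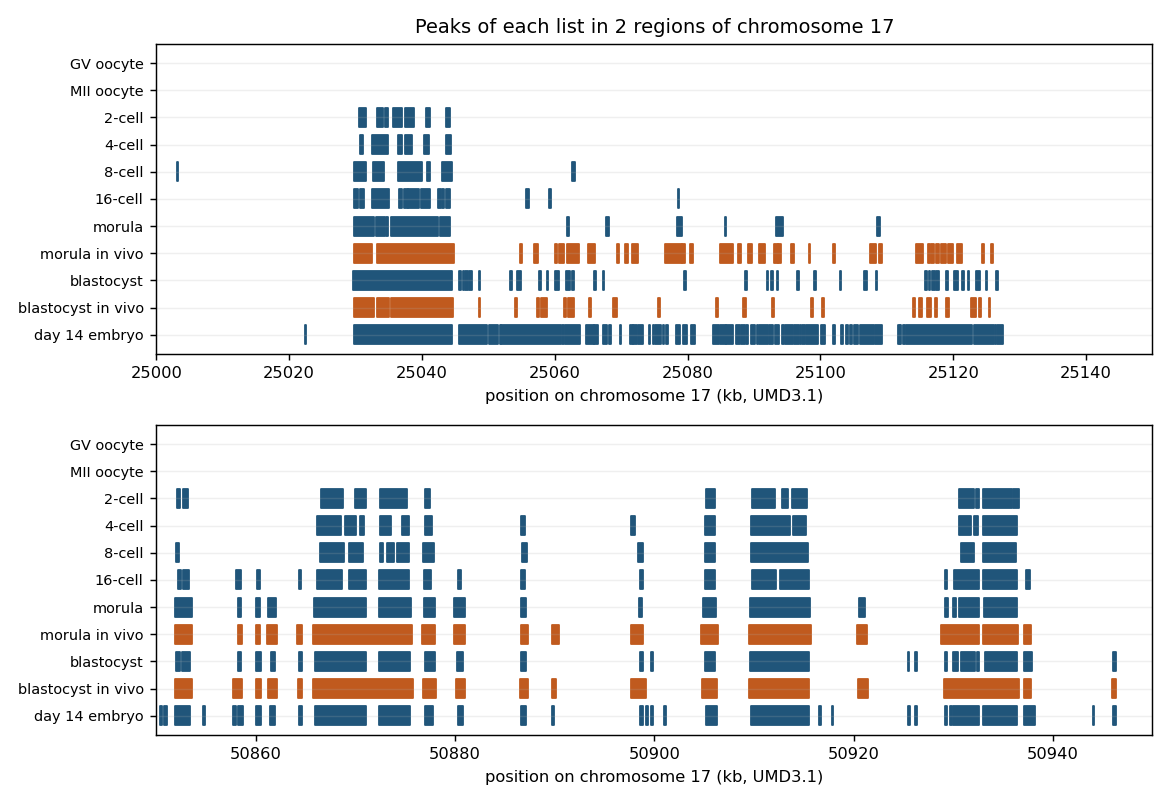
Peaks of each list (vertical axis, in vivo lists in orange) along the 2 regions of chromosome 17 (horizontal axis, position in kb). Bars are peaks to scale; both oocyte lists are empty in these spans and all 9 embryo lists hold peaks.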

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

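The tests on library number, on split peaks and on narrow peaks were chosen after the results were seen, and the tests of blastocyst peaks against morula peak widths were written before. The measures listed first were selected because the in vivo list lay above the other list at one stage and below it at the other. These differences are between single lists and were not tested. Covered length in vivo was 0.647 times that of the list without the label in morulae and 1.17 times in blastocysts. The widest peak in vivo was 1.05 times as wide in morulae and 0.673 times in blastocysts. The density on chromosomes 18, 19 and 25 relative to the other chromosomes was 1.09 times as high in vivo in morulae and 0.889 times in blastocysts.

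Both blastocyst lists were short beside the morula and day 14 lists. Between the in vivo lists the number of merged libraries does not account for this, since the morula list held 22.0 times as many peaks as the blastocyst list with 4 libraries each. The other blastocyst list was merged from 3 libraries and the other morula and day 14 lists from 6 each, so library number may play a part there. Without the label, a thinned sample of the widest morula regions was argued against. Morula peaks overlapped by blastocyst peaks had a median width of 592 bp, below the 649 to 980 bp of random placements, and 411 bp against 590 to 1022.5 bp without recurring regions. In vivo the median was 740 bp against 547 to 923 bp at random; a value inside that range had been set to count against thinning, but random placements put only 2.64% of these peaks on a morula peak, and so wide a range leaves it open. Lower depth, lower library quality and a true difference of stage may each play a part, and the lists cannot separate them.

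The day 14 list held several times the peaks of the morula list. Splitting of wide regions into peaks closer than 500 bp was argued against as the whole account. After such peaks were joined the ratio was 3.54 (284318 against 80374 regions, from 372509 against 88858 peaks). Splitting with wider gaps was not tested. Narrower peaks could account for part of it, as the ratio was 1.74 among peaks of at least 268 bp (146769 against 84580), which lies between the bounds set for and against that explanation. At the minimum of 329 bp set before the data were examined, the numbers were closer, with 108850 against 71395 peaks. Depth and the calling threshold stay open, as does a biological difference of stage, which was not tested.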

How the results depend on the processing

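The alternatives without recurring regions and with matched widths were chosen after seeing the data. No paired analysis was possible because each group was deposited as 1 merged list, so that the replicate numbers shared by the in vivo groups carry no values of their own. Score thresholds were not run, since the lists hold no score, and location, gene list and motif alternatives were not run without a genome of the build. Restricting the lists to autosomes and X removed no peak and so tested nothing. Joining peaks closer than 500 bp and leaving out recurring regions kept all 11 peak numbers within 1.5 times. Counting peaks of at least 329 bp left 324 in MII oocytes, 1336 in 2-cell embryos, 50423 in 16-cell embryos, 1044 in blastocysts and 108850 at day 14, as narrower peaks were left out. The GV list was then 9.03 times as long as the MII list, the morula list 68.4 times as long as the blastocyst list, and the in vivo blastocyst list 1.72 times as long as the other blastocyst list, a reversal from 0.762 times. Ratios of peak numbers for the other 7 comparisons stayed within 1.5 times. Under this minimum the covered length moved by over 1.5 times in 3 lists and stayed within that in 8.

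Shares are given for MII in GV, MII in 2-cell, 2-cell in 4-cell, 4-cell in 8-cell, 8-cell in 16-cell, 16-cell in morula, blastocyst in morula, blastocyst in day 14, in vivo morula in morula and in vivo blastocyst in blastocyst, in this order. With 50% of both peaks shared they were 11%, 12.9%, 17.9%, 14.9%, 26.1%, 22.8%, 17.6%, 39.4%, 36.2% and 22.3%, lower by construction. With the longer list drawn down to the shorter they were 3.12%, 6.42%, 12%, 3.31%, 35.6%, 40.5%, 1.27%, 0.563%, 39.8% and 27.5%, as fewer peaks can be met. Without recurring regions they were 1.31%, 0.374%, 7.42%, 24.8%, 44.3%, 46.5%, 14.4%, 44.2%, 60.3% and 19%; this setting removes any region present in several short lists, whatever its nature. Widening by 250 bp kept both MII shares and the in vivo blastocyst share within their intervals and gave 28.3%, 37.4%, 50.5%, 52.5%, 37.6%, 64.3% and 65.7% for the others. Observed over random was 12.5, 16.8, 12.1, 2.12, 2.46, 2.02, 1.18, 1.56, 2.56 and 16.7 with positions drawn from peaks of the other lists, above 1 and above all 100 draws in all 10 comparisons. The ratios are lower because such positions already lie in peaks. The pool held the 372509 day 14 peaks in every comparison except that of blastocyst and day 14. It thus differed between comparisons, and these ratios cannot be ranked against each other. The draws placed each peak on its own, so for clustered peaks their range may be too narrow. They kept recurring regions and were not repeated without them. Shares without these regions were below the background of the draws for MII in GV (1.31% against 1.53%), MII in 2-cell (0.374% against 1.39%) and blastocyst in morula (14.4% against 27.8%). The others were above it, so the direction is not shown to hold without recurring regions. Sharing in the reverse direction moved beyond its interval in all 10 comparisons with 50% of both peaks shared and in all 10 without recurring regions, and in 8 with widened peaks. At matched widths the 5 shares of unshared peaks found in a further list were higher than without matching, and each stayed below the share of the shared peaks. Recurring regions were not left out of these 5 shares. Unknown depth limits every peak number, and a peak absent from a list is not shown to be closed chromatin.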

Other observations

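The tests on recurring regions and the windows named here were chosen after the results were seen. Across all lists the peaks formed 482097 regions, of which 83.0% were in 1 list and 105 in all 11. In neither oocyte list but in all 9 embryo lists were 95 regions, of which 23 (24.2%) lay on chromosome 17, which makes up 2.82% of the length spanned. Of these, 10 lay between 51 and 52 Mb and 6 between 50 and 51 Mb. Of the 421 regions found in the 2-cell, 4-cell and both blastocyst lists, 244 (58.0%) were also in the GV list, and windows differed in this: none of the 16 such regions between 50 and 52 Mb on chromosome 17 were in the GV list, 4 of 24 between 145 and 146 Mb on chromosome 1, 2 of 13 between 28 and 29 Mb on chromosome 27, and 38 of 42 between 0 and 1 Mb on chromosome 14.

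Most lists held more peaks in the last decile of the autosomes than in the first, and the ratio was highest in GV oocytes and day 14 embryos. In GV oocytes 23.1% of autosomal peaks lay in the last decile and 8.17% in the first, a ratio of 2.83, and at day 14 these shares were 18% and 8.45%, a ratio of 2.13. The ratio was 1.26 in MII oocytes, 1.18 in 2-cell, 1.48 in 4-cell, 1.08 in 8-cell and 1.31 in 16-cell embryos, 1.44 in morulae and 1.30 in in vivo morulae. In blastocysts it was 0.806 and in in vivo blastocysts 0.581. Single windows weigh on these values. Of 3033 autosomal blastocyst peaks, 129 lay between 0 and 1 Mb on chromosome 14, in the first decile. A further 120 lay between 145 and 146 Mb on chromosome 1, in the last decile. In vivo each of these windows held 60 peaks. The ratios were not computed without them. The last decile held 18.7% of the 2-cell peaks, whose first decile held 15.9%. Of the GV peaks, 29.5% overlapped an 8-cell peak, 12.5 times the random mean, and 53.1% a peak of the longer day 14 list, 4.95 times the random mean.

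In the 6 short lists, 511 regions recurred in 4 or more lists. All of them were found in at least 1 of the 5 long lists, and 345 (67.5%) in all 5. They were clustered, with 51 between 0 and 1 Mb on chromosome 14, 33 between 30 and 31 Mb on chromosome 29 and 28 between 6 and 7 Mb on chromosome 6. Sequence repeats collapsed in the assembly may contribute, since 43.2% of the regions lay in 1 Mb windows with 5 or more of them, against at most 1.96% at random, but most of the regions lay outside such windows, and clustered genes would give the same grouping. Promoters open at every stage should be denser on the gene-dense chromosomes 18, 19 and 25. By regions the density there was lower, at 0.556 times that of the rest (interval 0.332 to 0.877). By 1 Mb windows holding any of the regions it was 1.02 times (interval 0.546 to 1.75). Clustered regions are not independent, so the interval by regions is too narrow, and the clusters weigh on its ratio. Density by chromosome thus leaves promoters open for all or part of the regions. Without a genome of the build the explanations cannot be told apart, and the share of peaks overlapping the 511 regions was 21.1% in blastocysts, 25.1% in MII oocytes and 0.205% at day 14.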
